A study of Homo sapiens with 6 samples.

How the data were processed

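RNA levels were measured on Illumina HumanHT-12 V4.0 arrays in 6 samples labelled as the breast cancer line HCC1954, 3 given vehicle and 3 given a compound called TBK1 inhibitor II, each for 3 days. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was extracted with a column kit, its quality was checked on a Bioanalyser, and it was labelled with biotin. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

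The deposited table of the whole series gives, per the file headers, a signal intensity on a linear scale and a detection p-value for each of 47321 probes on each array. Its values were not normalized between arrays, since the array medians differed. The submitters' processing notes name lumi and give no version. The deposited processed value table is on a log2-like scale and gives each array the same distribution of values, with column medians of 7.16. Within each array its order was the same as that of the signal intensity (Spearman rho 1). Differences between the groups in it followed those of log2 intensity after quantile normalization without background correction, across probes (r = 0.997, slope 0.930), more closely than those of the values used here (r = 0.913, slope 0.536). It was therefore not centred per gene, and its direction was that of the signal. The exact transformation and the log base are not given in the sources used here. Differences in the processed values are read below as log2 fold changes because of that log2-like scale. Their sizes and the count of genes changed at least 2-fold taken from them rest on this reading.

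The signal intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected with the neqc function, whose normexp model took the negative control distribution from the detection p-values and added an offset of 16, followed by quantile normalization and log2. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 19958 in all. A probe detected only on the 3 arrays of 1 group was thus kept too, through the group where it was high. Background correction of this kind widens fold changes of dim probes, and quantile normalization sets the whole distribution of each array equal, so a shift of most genes in 1 direction would be removed.

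Probe names came from the platform annotation, in which 30112 probes had 1 gene symbol, 8 had several and 17201 had none. Symbols were updated through the gene ID with the RefSeq gene table of assembly GRCh38.p14, which matched 30073 probes. The build behind the array is not given in the sources used here, so no coordinates are printed. Where a gene had several kept probes, 3054 genes, the probe with the highest mean over the 6 arrays stood for it, which left 11582 genes. Of the kept probes, 4551 had no symbol. They were part of the same fit, and their p-values were adjusted over all 19958 kept probes.

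Inhibitor and vehicle samples were compared with limma's lmFit and eBayes on all kept probes, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the genes, with a threshold of 0.05. Fold changes are inhibitor over vehicle, and their standard errors are limma's moderated ones. All adjusted p-values of single genes are from this limma fit. A gene not detected on any array of a group has only an upper bound there. For it the fold is given as at least the mean of the detected group over a mean that takes, for each array of the dim group, the higher of the lowest normalized level among detected probes and the probe's own level.

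Before the data were examined, 36 gene lists were fixed from textbook knowledge, covering the drug target, growth signalling, the cell cycle, stress and metabolism, and cell type. The 33 lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from each list and with fry. The genes named in the text were also chosen by a rule fixed beforehand. They are the 10 largest fitted rises and 10 largest fitted falls among genes past the threshold whose group values did not overlap, 12 genes always given, and up to 4 members past the threshold from each list, or up to 2 with the smallest p-value where none passed. Placeholder symbols were left out. Genes outside that rule are said to be so where they appear.

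The procedure was tested on simulated data made from these arrays' levels and spread, in which 200 of 11582 genes were changed. A log2 change of 1 was recovered for 84% of the changed genes of that size and a log2 change of 2 for 100%, with 5 false calls among 189, and the list shifted on purpose was the only list called. The simulated spread was drawn independently for each probe, so this run cannot show how often correlated genes lead to false list calls. Precision is limited by the number of arrays, 3 in each group. The alternatives tried, listed before the data were examined, were the deposited processed values, other background corrections, offsets, normalizations and filters, other rules for several probes of a gene, other estimates of the spread, a replicate block, each array left out in turn, and other list tests.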

Results

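The series asked how gene expression in a HER2-positive breast cancer line responds to inhibition of TBK1, a kinase of innate immune signalling that its title names as a target in this cancer. HCC1954 is a line from a breast carcinoma with amplified ERBB2, the gene of the receptor HER2. Samples labelled HCC1954 were given vehicle (n = 3) or TBK1 inhibitor II, a small molecule named for its target (n = 3), for 3 days. The median signal intensity was 98.5, 101.7 and 138.1 on the arrays of vehicle replicates 1, 2 and 3, and 110.7, 117.3 and 130.7 on those of inhibitor replicates 1, 2 and 3. Detected probes numbered 18325, 19857 and 20127 in the vehicle samples and 19676, 20741 and 20598 in the inhibitor samples. Correlations of normalized log2 levels across probes were 0.975 to 0.985 within the vehicle group, 0.988 to 0.991 within the inhibitor group and 0.968 to 0.981 between the groups.

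Transcripts of the ERBB2 region and of breast epithelium were in part detected and in part not, in both groups. ERBB2 was detected on all 6 arrays, at a moderate level (median signal intensity 405.3, 59.4th percentile of genes by mean level). Of the 12 genes of its region on the array, ERBB2 included, 9 were detected on all 6 arrays, while GRB7 was detected on 0. Of those detected, STARD3, MIEN1 and PGAP3 lay at the 41.7th, 26.4th and 31.6th percentile. The 9 measured genes of the region had a median at the 39.5th. Detection of these genes does not by itself show an amplified region. The epithelial genes KRT8, KRT18, EPCAM and CDH1 were detected on all 6 arrays, with median signal intensities of 172.3, 199.5, 194.3 and 164.7. The keratins KRT7, KRT19, KRT5 and KRT14 and the tight junction gene CLDN3 were detected on 0. The genes VIM, CDH2 and NEFM, known from mesenchymal and neural cells, were also detected on all 6 arrays, with median signal intensities of 5667, 1407 and 2003. Of the luminal epithelial list 5 of 17 genes on the array were detected on all 6 arrays, and of the basal epithelial list 2 of 11. The corresponding counts were 3 of 11 for fibroblast markers, 1 of 13 for leukocyte and endothelial markers, and 12 of 12 for housekeeping genes. For the mesenchymal transition list, which holds VIM and CDH2, the count was 7 of 17 (41.2%), and 6 were detected on 0. Of all genes on the array 48.9% were detected on all 6, so VIM and CDH2 do not stand for that list. Apart from ERBB2 and VIM, the genes of this paragraph were named after their values were seen. Because the epithelial genes and GRB7 not detected go against the label, and the moderate ERBB2 level leaves it in doubt, the samples are called by their label here, and each direction given is a difference between samples labelled HCC1954.

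**Figure D1:**
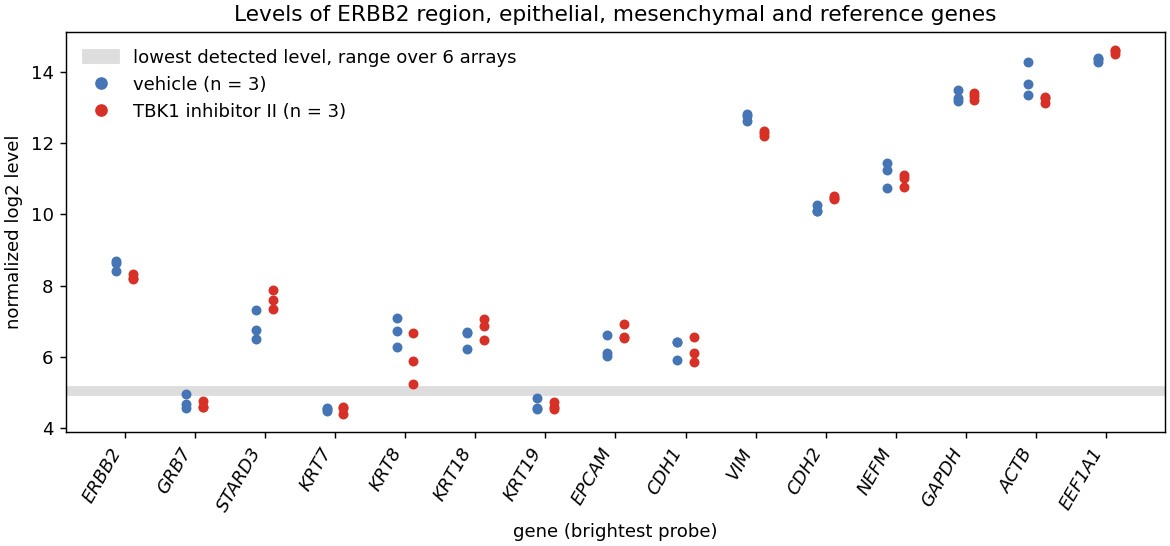
Normalized log2 levels (vertical axis) of 15 genes (horizontal axis, brightest probe of each) on the 6 arrays, 3 vehicle and 3 inhibitor, 1 point per array. The grey band is the range over the arrays of the lowest level among detected probes, 4.94 to 5.16, and all points of GRB7, KRT7 and KRT19 lie within or below it and all points of ERBB2, STARD3, KRT8, KRT18, EPCAM and CDH1 above it, while different probes are not comparable in level with each other.

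After 3 days with the inhibitor, 631 of 11582 genes tested (5.45%) differed from vehicle, 416 higher and 215 lower, and 198 of them by at least 2-fold. With the background correction used, the largest rise among genes detected in both groups was that of CGA, which encodes the common alpha subunit of glycoprotein hormones (probe ILMN_1734176), with a log2 fold change of 3.46 ± 0.22 (SE, n = 3 per group, limma adjusted p = 0.000384). CXCR4, the receptor of the chemokine CXCL12, and CCL2, a chemokine that attracts monocytes, were not detected on any vehicle array and were detected on all 3 inhibitor arrays with the probes used. CCL2 was at least 4.77-fold higher (limma adjusted p = 0.000384). CXCR4 was at least 4.89-fold higher on the probe used (adjusted p = 0.000411) and at least 2.04-fold on its other kept probe, and its remaining probe was detected on 1 array of each group. These bounds hold for the background correction used, since with the deposited processed values the log2 fold changes were 1.01 for CXCR4, 0.93 for CCL2 and 1.83 for CGA, each still past the threshold. NR4A2, an orphan nuclear receptor induced early by many stimuli, rose by 1.90 ± 0.19 on the log2 scale (adjusted p = 0.00640). LRRC26, an auxiliary subunit of potassium channels, rose by 1.98 ± 0.16 (adjusted p = 0.00120), and its other kept probe by 1.52, with detection on 1 of 3 vehicle arrays. With the deposited processed values these rises were smaller, 0.88 for NR4A2 and 0.67 for LRRC26.

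Further large rises were those of the zinc finger gene ZCCHC12 (2.09 ± 0.24, adjusted p = 0.0103), AKR1C3, an aldo-keto reductase of steroid and prostaglandin metabolism (2.06 ± 0.26, adjusted p = 0.0128), and CA8, a carbonic anhydrase relative without catalytic activity (1.71 ± 0.22, adjusted p = 0.0130). AKR1C3 and CA8 were each detected on 1 of 3 vehicle arrays, so the size of their rise is measured against a group mostly at background. The deposited processed values gave 0.72 for AKR1C3 and 0.57 for CA8, which passed the threshold in 16 and 17 of 19 alternative settings, and 1.95 for ZCCHC12, more than for CGA. The small nucleolar RNA SNORD13 rose by 2.03 with a wider error of 0.44 (adjusted p = 0.0348). APOLD1, an early-response gene of endothelial cells, was not detected on any vehicle array and was at least 2.76-fold higher (adjusted p = 0.0166), a bound for the background correction used. With the deposited processed values APOLD1 had a log2 fold change of 0.53, and it passed the threshold in 16 of 19 alternative settings.

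With the background correction used, the largest fall among genes detected in both groups was that of ACY1, an enzyme that removes acetyl groups from amino acids (probe ILMN_1683883), with a log2 fold change of -1.66 ± 0.22 (SE, n = 3 per group, limma adjusted p = 0.0130). Lower levels were also found for CITED1, a transcriptional co-regulator (-1.63 ± 0.28, adjusted p = 0.0235), and AMOT, a junction protein that binds YAP (-1.39 ± 0.17, adjusted p = 0.0109). GSTO2, a glutathione transferase, and FAH, the last enzyme of tyrosine breakdown, each had a log2 fold change of -1.43 (adjusted p = 0.00938 and 0.0144). TTC12 (-1.59), LINGO1 (-1.55) and LRFN4 (-1.48) fell as well, with adjusted p-values of 0.0128, 0.0298 and 0.0128. The sizes and their order depend on the background correction, since the deposited processed values gave -0.62 for ACY1, -1.39 for CITED1 and -1.34 for AMOT. They gave -0.99 for GSTO2, -0.90 for FAH, -0.77 for TTC12, -0.77 for LINGO1 and -0.72 for LRFN4. The probes of a pair of genes disagreed. TERF1, a protein of telomeric DNA, had -1.58 on the probe used and 0.01 on its other kept probe, and OSCP1 had -1.62 and -1.25 on its brighter and next probe but 0.05 on the remaining one, with detection on 2 of 3 inhibitor arrays for the probe used. With the deposited processed values TERF1 had -0.97 and OSCP1 -0.56. Of the 176 changed genes with several kept probes, 149 had all probes in the same direction.

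**Figure D2:**
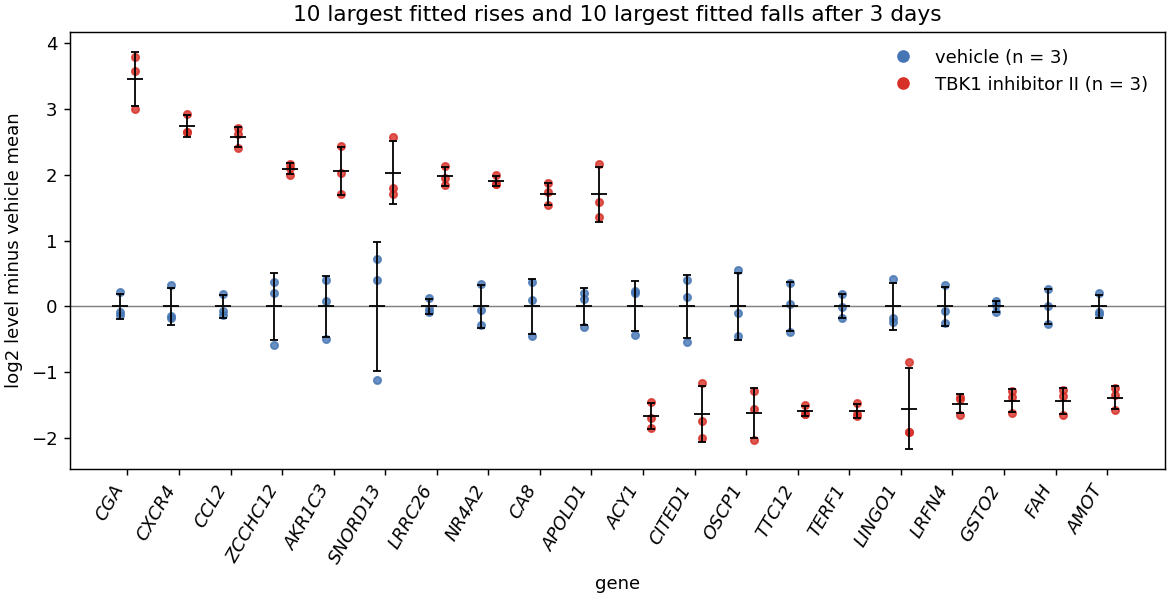
Normalized log2 level minus the vehicle mean (vertical axis) for the 10 genes with the largest fitted rise and the 10 with the largest fitted fall (horizontal axis), as points for each of 3 vehicle and 3 inhibitor arrays, with the group mean and SD as bars. CGA shows the largest plotted difference, 3.46, and the inhibitor points of every gene lie on 1 side of its vehicle points, although the vehicle levels of CXCR4, CCL2 and APOLD1 were not above background, so that the distances plotted for them are not folds.

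The target and most of the genes fixed for report did not pass the test. TBK1 had a log2 fold change of 0.10 ± 0.17 (SE, limma adjusted p = 0.753), and its relative IKBKE, detected on 2 arrays of each group, -0.01 ± 0.28 (adjusted p = 0.980). ERBB2 had -0.34 ± 0.15 (adjusted p = 0.217) and RELA, a subunit of NF-kB, -0.50 ± 0.16 (adjusted p = 0.0960). The cell cycle genes CDKN2A (-0.32), CDKN1A (0.09), RB1 (0.50), CCND1 (-0.32) and MKI67 (0.06) had adjusted p-values of 0.322, 0.828, 0.331, 0.296 and 0.871, and MKI67 was detected on 2 vehicle arrays and 3 inhibitor arrays. The cytokine gene CXCL8 had 0.02 (adjusted p = 0.961), and IL6 was detected on 0 of the 6 arrays. NFKB1, which encodes another NF-kB subunit, rose by 0.98 ± 0.18 (adjusted p = 0.0288). The level of a kinase transcript does not measure the activity of the kinase.

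Of the NF-kB target list, 5 of 17 measured genes rose, none fell and 12 did not pass. Besides CCL2 and NFKB1 they were NFKBIA, the inhibitor of NF-kB that NF-kB itself induces (1.31 ± 0.15, limma adjusted p = 0.00938), the chemokine gene CCL20 (1.18 ± 0.23, adjusted p = 0.0298, detected on 2 of 3 vehicle arrays) and IER3 (0.92 ± 0.21, adjusted p = 0.0414). Over the alternative settings the log2 fold change of CCL20 ranged from 0.35 to 1.40, past the threshold in 15 of 19. Adjusted over the list alone, 6 rose. The list's median log2 fold change was 0.22, and its camera adjusted p was 0.0152, against an adjusted p = 0.433 with an estimated correlation.

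Of the interferon-stimulated genes, 4 of 19 measured fell, 0 rose and 15 did not pass. They were BST2, which tethers budding viruses (-1.06 ± 0.14, limma adjusted p = 0.0150), IFI35 (-1.02 ± 0.21, adjusted p = 0.0320), the ubiquitin-like ISG15 (-0.87 ± 0.17, adjusted p = 0.0298) and OASL (-0.81 ± 0.17, adjusted p = 0.0345). Adjusted over the list alone, 4 fell and 1 rose, CXCL10, which was named after its value was seen and had 0.66 (adjusted p = 0.0748 over all genes). The list's median was -0.11 with quantile normalization and 0.10 with median centring, where the median of all genes was 0.243. Its camera adjusted p was 0.0217, against an adjusted p = 0.433 with an estimated correlation, and the call ended with median centring (0.0613), without vehicle replicate 1 (0.0663) and with a detection p under 0.01 required on all 6 arrays (0.0734). In the list of the TBK1 complex and innate sensing, none of the 18 measured genes passed. Its smallest p-values were those of STING1 (-0.87 ± 0.23, adjusted p = 0.0582) and TBKBP1 (-0.63 ± 0.19, adjusted p = 0.0875, detected on 2 of 3 inhibitor arrays). Over the alternative settings STING1 ranged from -1.08 to -0.33 and passed the threshold in 9 of 20, and TBKBP1 passed in 0 of 18.

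The lists of the cell cycle had opposite camera directions. Of 29 measured genes of G1/S and DNA replication, 2 fell, 0 rose and 27 did not pass, with 26 log2 fold changes below 0 and a median of -0.24. MCM5, a subunit of the replicative helicase, fell by 0.93 on the log2 scale (limma adjusted p = 0.0423) and CCNE1, cyclin E1, by 0.66 (adjusted p = 0.0457). Adjusted over the list alone, 3 fell. This list had the smallest camera adjusted p, 0.000234, against an adjusted p = 0.433 with an estimated correlation, and its median stayed below 0 with median centring, at -0.06 against 0.243 for all genes. Of 30 measured genes of G2/M and mitosis, 1 rose, 0 fell and 29 did not pass, with 24 log2 fold changes above 0 and a median of 0.25. BIRC5, the mitotic protein survivin, rose by 0.71 ± 0.15 (adjusted p = 0.0320), and it was also the only gene past the threshold when adjusted over the list alone. The camera adjusted p was 0.0172, against an adjusted p = 0.685 with an estimated correlation, and the call ended with median centring (0.147) and without vehicle replicate 1 (0.0663).

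Of 6 measured histone genes known to give polyadenylated transcripts, 3 rose and 3 did not pass, and all 6 log2 fold changes were above 0. The 3 were H2BC12 (1.04 ± 0.18, limma adjusted p = 0.0235), H2AC18 (0.89 ± 0.21, adjusted p = 0.0457) and H2BC21 (0.67 ± 0.16, adjusted p = 0.0454), and the same number passed when adjusted over the list alone. H2BC21 was detected on 1 of 3 vehicle arrays and passed the threshold in 4 of 19 alternative settings, with log2 fold changes from 0.17 to 0.76. The camera adjusted p was 0.0172, against an adjusted p = 0.433 with an estimated correlation, and it was 0.0537 with the deposited processed values and 0.0580 without the filter on dim probes.

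**Figure D3:**
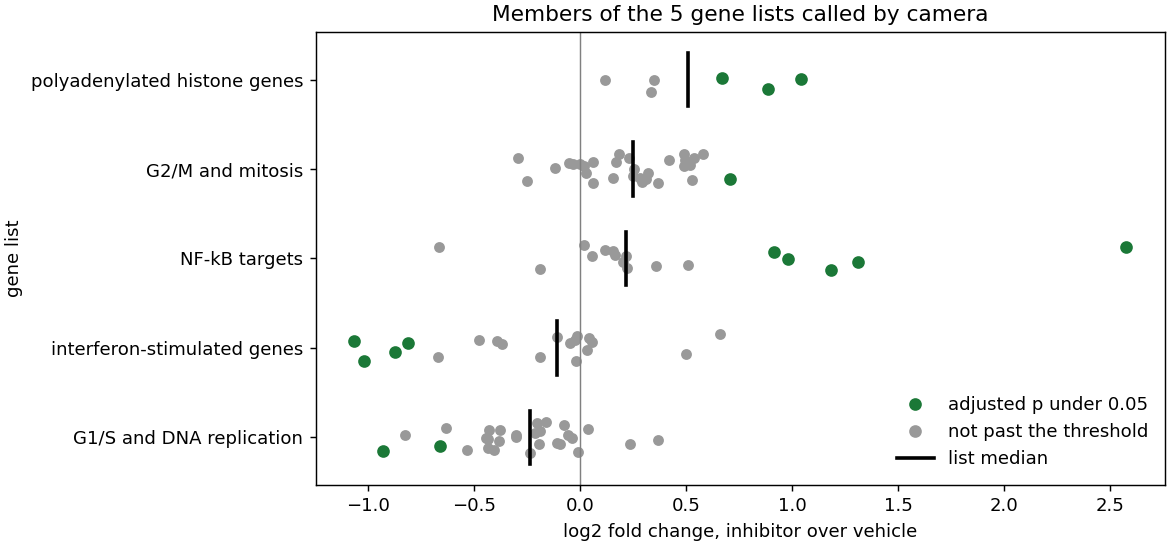
Log2 fold changes, inhibitor over vehicle (horizontal axis), of the measured members of the 5 gene lists called by camera (vertical axis), with members past the adjusted p threshold in green, the others in grey and the list median as a bar. Medians run from -0.24 for G1/S and DNA replication to 0.51 for the polyadenylated histone genes, with that of the interferon-stimulated genes at -0.11, which changed to 0.10 with median centring.

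Growth and stress lists held few genes past the threshold. CCN1, a matricellular protein and YAP target, rose by 1.65 ± 0.23 (SE, limma adjusted p = 0.0166), the only riser among 9 measured YAP/TAZ targets, with 1 riser and 1 faller adjusted over the list alone (camera adjusted p = 0.457). Among 19 FOXO and PI3K feedback genes the repressor BCL6 rose (1.46 ± 0.18, adjusted p = 0.0109) and the ubiquitin ligase subunit FBXO32 fell (-0.74 ± 0.17, adjusted p = 0.0394), the same counts as over the list alone (camera adjusted p = 0.245). Of 11 genes of MAPK output 2 rose, IER3 and FOS, which was not detected on any vehicle array and was at least 1.58-fold higher (adjusted p = 0.0371, but past the threshold in 10 of 18 alternative settings and at 0.36 on the log2 scale with the deposited processed values), and 2 rose adjusted over the list alone (camera adjusted p = 0.600). Of 11 NRF2 targets AKR1C3 rose and the quinone reductase NQO1 fell (-1.17 ± 0.26, adjusted p = 0.0389), with 1 each adjusted over the list alone (camera adjusted p = 0.931). NQO1 and ALDH1A3 (-0.73 ± 0.16, adjusted p = 0.0402) fell among 7 AHR targets, with 2 fallers and 1 riser adjusted over the list alone (camera adjusted p = 0.847). Of 10 senescence-associated secreted factors 2 rose, CCL2 and STC1 (0.97 ± 0.19, adjusted p = 0.0298), with 3 risers and 1 faller adjusted over the list alone (camera adjusted p = 0.596).

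Of 9 CDK inhibitors and pocket proteins CDKN2D (0.82 ± 0.19, limma adjusted p = 0.0438) and CDKN2B (0.68 ± 0.15, adjusted p = 0.0414) rose, also 2 adjusted over the list alone (camera adjusted p = 0.175). Of 19 genes of cholesterol biosynthesis 2 rose, INSIG1 (1.06 ± 0.25, adjusted p = 0.0435), a brake on sterol synthesis whose other kept probe had 0.08, and TM7SF2 (0.99 ± 0.18, adjusted p = 0.0288), and 2 rose adjusted over the list alone (camera adjusted p = 0.0730). GSDMB rose among 9 measured genes of the ERBB2 region, ERBB2 included (1.19 ± 0.23, adjusted p = 0.0297), where 3 rose adjusted over the list alone (camera adjusted p = 0.633). NPC1, the lysosomal cholesterol transporter, rose among 17 lysosomal genes (0.80 ± 0.17, adjusted p = 0.0316), with 2 adjusted over the list alone (camera adjusted p = 0.596). WIPI2 rose among 17 autophagy genes (0.77 ± 0.16, adjusted p = 0.0316), also 1 adjusted over the list alone (camera adjusted p = 0.633).

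In the remaining lists no gene passed over all genes tested, and their camera adjusted p-values lay between 0.0730 and 0.931. Among them, 21 ATF4-responsive genes had 1 riser and 1 faller adjusted over the list alone, as had 21 genes of glycolysis and hypoxia, and 6 ERBB receptors and ligands had 1 riser. None passed over the list alone among the genes of the TBK1 complex, MHC class I presentation, p53 targets, apoptosis, fatty acid synthesis, the unfolded protein response, oxidative phosphorylation, ribosome biogenesis, ribosomal proteins, luminal epithelium, squamous differentiation, mesenchymal transition, heat shock or housekeeping. Of the 28 lists not called, 6 had a median, a mean and a camera direction that were not all of 1 sign, among them the secreted factors (median -0.01, mean 0.33) and the AHR targets (median 0.19, mean -0.09). Of the 33 lists tested, 5 were called with the preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move 1 way without comparing them with other genes, 8 were called. Those called by fry alone were the secreted factors (higher, fry adjusted p = 0.0238), fatty acid synthesis (lower, 0.0243) and the YAP/TAZ targets (higher, 0.0267).

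The number of genes past the threshold depended on single arrays. It was 347 without vehicle replicate 1, 435 without vehicle replicate 2, 218 without vehicle replicate 3, 37 without inhibitor replicate 1, and 4 without inhibitor replicate 2 and also without inhibitor replicate 3, and with median centring the split was 674 higher and 36 lower (94.9% higher, against 65.9% with quantile normalization).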

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

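The report above used only probes with a gene symbol. Among the 4551 kept probes without a symbol in the annotation used here, limma called 116 at the same adjusted threshold, 71 higher and 45 lower with the inhibitor, which is a signal in data outside the comparison of named genes. Their p-values were adjusted over all kept probes, and those of the named genes over the genes alone. No explanation was tested for them.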

How the results depend on the processing

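All alternatives were listed before the data were examined. All 631 genes kept their direction in each of the settings with a single value per gene that tested them, except that 630 of 631 did without a filter. With an array left out or array weights this outcome was fixed, since the groups of all 631 did not overlap. A trended and robust spread and the replicate block leave the fold changes as they were. Of the called lists none changed its camera direction.

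Genes changed (higher, lower) numbered 1351 (814, 537) with the deposited processed values, 1246 (761, 485) with normexp without detection p-values and an offset of 50, 1364 (821, 543) without background correction, 1174 (724, 450) with the offset alone set to 50, 1240 (762, 478) with a trended and robust spread, 970 (613, 357) with array weights and 894 (506, 388) with a detection p under 0.01 on all 6 arrays. With median centring they were 710 (674, 36), and the median of all genes moved to 0.243. Genes changed at least 2-fold numbered 26 with the deposited processed values, 57 with normexp without detection p-values and an offset of 50, 36 without background correction, 76 with the offset alone set to 50, 426 with median centring and 110 with a detection p under 0.01 on all 6 arrays. A larger offset shrinks folds of dim probes by construction, and for the other settings the cause was not tested. The setting without detection p-values and that with a detection p under 0.01 on all 6 arrays each changed a pair of choices together. The processed values shared 518 of the 631 calls and median centring 407. Sizes of single genes moved as well. Over the alternative settings the lowest log2 fold changes were 0.70 for BCL6, 0.49 for GSDMB and 0.35 for WIPI2, and the smallest fall of IFI35 was -0.47.

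With 1 array left out, genes changed ranged from 4 to 435, genes higher from 4 to 310, genes lower from 0 to 128, genes changed at least 2-fold from 4 to 226 and lists called from 3 to 7. These fits have fewer samples. The replicate block gave 40 genes (28 higher, 12 lower), all 40 of them at least 2-fold, and 7 lists. The numbers were not taken to pair the samples, since deviations of same-numbered samples correlated at -0.142, 0.0204 and 0.118 and 2 of 6 samples were closest to their own number. Lists called numbered 3 with median centring, 3 with a detection p under 0.01 on all 6 arrays, 0 with an estimated correlation and 8 with fry, against 5. Under that stricter filter the histone list had under 5 measured genes and gave no value, and otherwise the cause was not tested.

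Of the genes the text names, 4 changed sign under some setting, and none of these was called in the setting reported or under that alternative. IKBKE had 0.0023 with the offset alone set to 50 and 0.070 with median centring. CDKN1A had -0.050 with array weights. MKI67 had -0.044 with cyclic loess and -0.060 with array weights, and CXCL8 -0.020 and -0.045. With 1 array left out their ranges were -0.32 to 0.17 for IKBKE, -0.080 to 0.21 for CDKN1A, -0.033 to 0.18 for MKI67 and -0.13 to 0.14 for CXCL8. The chip could not be used as a block, since none was named in the files used here. Signal over background limits the dimmest genes, such as FOS, CXCR4, CCL2 and APOLD1, to bounds.

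The 6 samples form 10 splits into groups of 3, too few for a share under 0.05. The real split, 1 of 10 with a result as large, gave 631 genes changed, 198 at least 2-fold and 5 lists. The highest of the other splits gave 0, 0 and 3. Each of the other splits mixes vehicle and inhibitor samples in both groups, so a real difference would widen the spread and lower their counts. They are therefore not a measure of what chance alone gives. At an unadjusted p under 0.05, 2829 genes passed in the real split, and 3644 genes (31.5%) had groups that did not overlap, against 10% by chance.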

Other observations

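The lists and single genes of this part were chosen after the top genes had been seen, and the test on ribosomal proteins was chosen after its result was known. Tests on members not seen before had their outcome stated first.

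CGA, NR4A2 and FOS, which were higher with the inhibitor, are known as genes that respond to cAMP through CREB. Of 18 further genes of this kind 11 were measured and 4 rose, PTGS2 (1.23 ± 0.18, limma adjusted p = 0.0172), DUSP1 (0.98 ± 0.19, adjusted p = 0.0288), FOSB (at least 1.70-fold, adjusted p = 0.0429) and VGF (at least 1.41-fold, adjusted p = 0.0359). The bounds hold for the background correction used, and with the deposited processed values FOSB had a log2 fold change of 0.23 and VGF 0.24. Over the alternative settings, FOSB passed the threshold in 6 of 19, VGF in 8 of 18, PTGS2 in 15 of 19 and DUSP1 in 14 of 20. The lowest log2 fold changes there were 0.44 for PTGS2 and 0.84 for DUSP1. These genes were dim, with a median at the 8.67th percentile of genes by level, 3 of 11 detected on all 6 arrays and 3 not detected on any vehicle array. All 11 log2 fold changes were above 0, with a median of 0.60, or 0.49 with the genes not detected in vehicle at their bound. Those 3 genes passed the filter on dim probes only through the inhibitor arrays, where they were high. The count above 0, the median and the list tests below thus rest in part on members selected by the outcome.

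CLK1, a kinase of splicing factors, was also higher (1.66 ± 0.17, limma adjusted p = 0.00659). Of 15 further measured transcripts that are held in the nucleus or encode SR-type splicing proteins, 3 rose, CLK4 (1.06 ± 0.23, adjusted p = 0.0340), PNISR (0.93 ± 0.18, adjusted p = 0.0295) and HNRNPDL (1.18 ± 0.27, adjusted p = 0.0414), whose other kept probe had -0.52. On the probes used, 14 log2 fold changes were above 0, with a median of 0.47.

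The cAMP/CREB-responsive members gave an unadjusted camera p of 4.44e-06 with the preset correlation and 0.0421 with an estimated correlation. The unadjusted camera p-values of the NF-kB target list were 0.000920 and 0.0234, in the same order. Of 10000 random lists matched on level, 2 had a median as high, but random lists do not carry the correlation of co-regulated genes. The camera p of the cAMP/CREB-responsive members was 0.000398 without background correction, where the median was 0.21, and 5.95e-05 with median centring. Most members lie near the floor, so neither background correction nor quantile normalization is excluded. A wider response of these genes may accompany the inhibitor, as a hypothesis found and tested on the same arrays. A difference in handling between the groups, or an effect of the compound on kinases other than TBK1, stays open and was not tested.

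The nuclear and splicing-related members gave an unadjusted camera p of 0.000129, or 0.0268 with an estimated correlation. Of 10000 matched random lists, which do not carry the correlation of co-regulated genes, 0 had a median as high. Background correction is argued against by 9.44e-06 without it, and quantile normalization by 3.7e-05 with median centring. A shared change of such transcripts may follow the inhibitor, as a hypothesis. RNA quality that differed between the groups stays open, since no value used here measures it and it would be confounded with treatment.

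The absence of GRB7 and part of the epithelial transcripts from detection in samples labelled HCC1954 was seen in vehicle as well as inhibitor samples. Of the genes of the ERBB2 region, ERBB2 included, 75% were detected on all 6 arrays, which does not measure amplification. No biological explanation from the design was tested. Shuffled probe names are argued against by a Spearman rho of 0.493 between mean levels of probe pairs of the same gene across 6691 genes, where the highest of 100 shuffles gave 0.0314. Of the ribosomal protein genes, 100% were detected on all 6 arrays. With a median at the 99.5th percentile of genes by level, they could be detected on dim arrays too, so they alone do not exclude dim arrays. Of 20045 genes on the array, 9798 were detected on all 6, among them KRT8, KRT18, EPCAM and CDH1 at median signal intensities of 164.7 to 199.5. These values argue against arrays too dim to show abundant transcripts. They do not speak to transcripts present at low levels. RNA from a non-epithelial source, such as another cell line, may account for the undetected transcripts. Of further epithelial genes 28.6% (4 of 14) were detected on all 6 arrays, against 48.9% of all genes, a difference in few genes that was not tested. GRHL2, ESRP1, RAB25, CLDN7 and ST14 were detected on 0. PERP, SPINT2, CDS1 and S100A14 were detected on all 6, at median signal intensities of 1288, 469.0, 410.9 and 184.7, and such a source would also have to express them. An embryonic kidney line of the HEK293 type could be such a source but was not decided. Of further genes of such lines 66.7% (6 of 9) were detected on all 6 arrays, against 48.9% of all genes, also not tested. They were CKB, UCHL1, TUBB2B, DPYSL3, CRMP1 and NES, at median signal intensities of 5311, 2647, 2308, 900, 157.7 and 133.8. MAP1B was detected on 4, ENO2 on 5 and PAX2 on 0. LIN28B and IRS4, seen before that list was written and left out of it, were detected on all 6 at 1514 and 276.3. On the normalized log2 scale IRS4 was lower on the inhibitor arrays (6.81 to 7.05) than on the vehicle arrays (8.19 to 8.40). For LIN28B the groups overlapped (10.48 to 10.69 and 10.30 to 10.52). A changed phenotype of the line itself was not tested.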
